A study of Mus musculus with 24 samples.

How the data were processed

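RNA of iNKT cells from mesenteric lymph nodes was measured by sequencing in 24 libraries, 3 for each combination of fecal transplant donor (wild-type or without CD1d), treatment (PBS or aGC) and sex. Per the labels, RNA came from a purification kit for single cells and small samples, and libraries were made by Nextera XT tagmentation, which does not keep the strand. The deposited values are expected counts per gene, in whole numbers, that the authors made with kallisto on the mouse build GRCm38 (mm10). The version of kallisto, the annotation release, the way transcripts were summed to genes, the sort gate and the number of mice per library are not given in the sources used here. The table held 55335 genes, of which 42058 had a count in at least 1 library. Of the 55335 genes 55154 had a symbol and a position in GENCODE M21, matched by Ensembl identifier without its version, and 181 had none. Among 60 pairs of genes whose annotated transcripts are identical in sequence and that held at least 100 counts, 59 had equal counts in every library, as when an estimator splits shared reads evenly.

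Genes were kept by edgeR's filterByExpr with the 8 groups (minimum count 10, minimum total 15), which left 15953. Counts were scaled by TMM, and edgeR's quasi-likelihood fit was made on all 24 libraries with 8 group means, so that the groups shared an estimate of the spread with 16 residual degrees of freedom. Each of the 8 comparisons was a contrast of these means that weighted the sexes, or the strata, equally. P-values were adjusted over all tested genes by Benjamini-Hochberg with a threshold of 0.05, without a fold threshold. All tests were two-sided, and SE is the log2 change divided by the square root of its F statistic. Levels are CPM with TMM scaling, and principal components used log2 CPM with a prior count of 2. Correlations between effects used 8359 genes with a mean log2 CPM above that of 10 CPM. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.

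The 33 gene lists, with 744 entries of which 673 were measured, were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives not said to be added later. The lists covered iNKT subsets, cytokines, receptors, transcription factors, metabolism, stress and markers of other cell types, and their members overlap. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera on 1 profile per group, described below, used the same preset, so its p-values do not measure how a list varies between cell pools. Of the 264 tests, 96 passed, of which 56 passed with an estimated correlation too, and the second adjusted p is printed wherever it missed the threshold. The text names, for each comparison, genes among the 8 largest rises and the 8 largest falls with an adjusted p under 0.05 and at least 5 CPM in a compared group. It also names up to 4 members of each list with the lowest adjusted p and up to 2 that did not pass. Ifng, Il4, Tbx21, Gata3, Zbtb16, Bcl6 and Mki67 are named in every comparison, Il10 and Il17a are named once for all comparisons, and Xist and the Y-linked genes are named for sex. Some genes that the rule covers are not reported here. Genes named in 1 comparison may be named in another.

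The fit was tested on simulated data with the spread between these libraries. Every group was given each gene's mean level over all 24 libraries, plus the planted changes, so real group differences were not simulated. For KO FT against WT FT after PBS it recovered 38 of 67 genes changed 1.5-fold, 50 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 7 of 14831 unchanged genes called. When a spread that all 3 libraries of a group share was added, the same fit called between 7556 and 7837 unchanged genes in the 8 comparisons, while a fit on 1 profile per group called between 2 and 7 in the 6 for which it was simulated. For that reason the counts of the 3 libraries of each group were summed, and edgeR was fitted to 8 profiles with terms for treatment, FT, their interaction and sex, which left 3 residual degrees of freedom. In the simulation this fit recovered between 12 and 52 of the 200 changed genes, with 12 for the response difference and 32 and 29 for FT after PBS and aGC. Its common biological coefficient of variation was 0.424, against 0.108 between the libraries of a group. Terms that it leaves out, such as sex by treatment, count as spread, so it can overstate the spread between cell pools. The shared spread of the simulation was taken from this fit, so the number of unchanged genes called follows from that choice. The libraries of a group still differed by more than counting error, with a chi-square per degree of freedom of 3.89 to 14.3 in the 24 pairs of replicates. Alternatives covered normalization, tool, filter, threshold, blocks by replicate number, covariates, gene length, single libraries and groups left out. Sequence variants, splicing and reads were not analysed here.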

Results

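RNA was sequenced from invariant natural killer T (iNKT) cells, T cells whose semi-invariant receptor binds lipids held by CD1d, from the mesenteric lymph nodes of C57BL/6J mice. The cells were sorted 24 h after an oral dose of 2 µg alpha-galactosylceramide (aGC), a lipid antigen of iNKT cells, in 200 µL PBS, or of PBS alone. The mice were offspring of dams that had been given feces of wild-type donors (WT FT) or of donors without CD1d (KO FT), where FT stands for fecal transplant. The libraries were also split by sex, which made 8 groups of 3 libraries, 24 in all. Total estimated counts ran from 9764931 to 37016768 per library, and 20765 to 26506 genes had at least 1 count. At these depths 3 counts in a library, the limit that a count of 0 allows, corresponded to 0.08 to 0.302 CPM (counts scaled to the library total), which covers counting error only. Mitochondrial genes held 0.148 to 0.373% of the counts of a library and the 20 most abundant genes 6.90 to 8.79%. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254, GRCm38/mm10), stood at 8.76 to 48.3 CPM in the 12 female libraries and at 0 to 0.645 CPM in the 12 male ones. The Y-linked helicase gene Ddx3y stood at 0 to 0.471 CPM in females and 41.2 to 78.6 in males, so the sex of every library fitted its label.

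The treatment separated the libraries most. The first principal component held 55.3% of the variance of 8748 genes, with the 12 PBS libraries between -34.4 and -25.5 and the 12 aGC libraries between 17.1 and 47.6. After aGC the WT FT males lay farthest out, at 46.5 to 47.6, followed by the WT FT females at 32.4 to 32.8, while both KO FT groups lay between 17.1 and 19.3. Libraries of the same group were correlated at r = 0.977 to 0.987 across genes in log2 CPM, and libraries of the 2 sexes with the same FT and treatment at r = 0.944 to 0.966. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values of the fits on 24 libraries measure the spread between these libraries, which may be technical. Each comparison thus also gives the genes passing with the 3 libraries of a group summed to 1 profile. The sexes served as replicates, or where sex was compared the FTs, treatments or both. The donor of the transplant cannot be told apart from the dam, the litter or the cage, which the labels do not give.

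**Figure D1:**
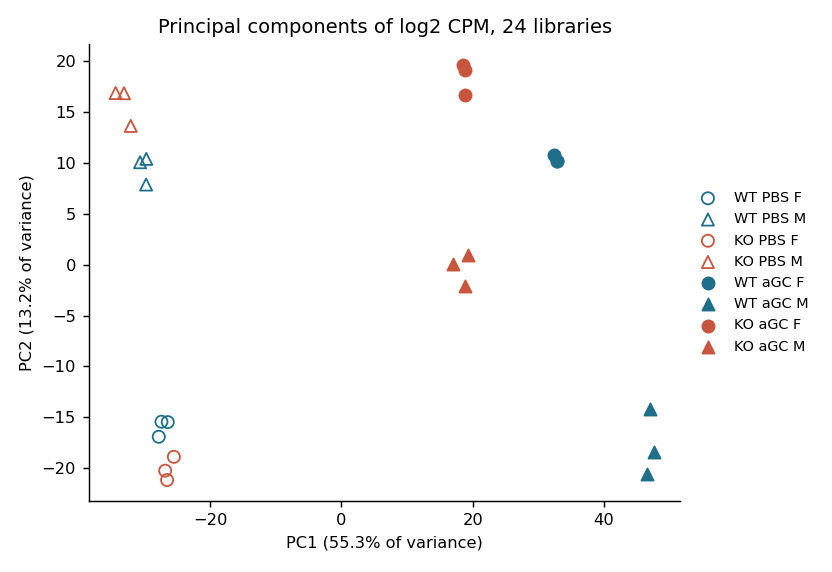
Principal components of log2 CPM of 8748 genes in 24 libraries, with the share of variance on each axis. Circles are females (F), triangles males (M), open symbols PBS, filled symbols aGC, blue WT FT and red KO FT. The PBS libraries lie at or below -25.5 on the first component and the aGC libraries at or above 17.1.

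The response of iNKT cells to antigen under the microbiota of wild-type donors was read from aGC against PBS in WT FT mice. In these mice genes rose for effector cytokines, transcription factors induced by the T cell receptor (TCR) and activation receptors. Ifng, which encodes interferon gamma (ENSMUSG00000055170.4, chromosome 10, 118441046 to 118445892), went from 18.4 ± 0.627 CPM (mean ± SD, n = 3) to 113 ± 4.20 in females and from 14.7 ± 0.288 to 133 ± 6.68 in males. Il4, the gene of the type 2 cytokine interleukin 4 (ENSMUSG00000000869.12, chromosome 11, 53602982 to 53618669), went from 56.7 ± 1.62 to 109.9 ± 5.08 CPM in females and from 31.0 ± 1.69 to 182 ± 5.47 in males. The chemokine gene Ccl1 reached 167 and 375 CPM after aGC, against 0.320 and 5.40 after PBS, and Ccl4 and Tnf rose 26.7-fold and 4.89-fold. Every aGC library lay above all 6 PBS libraries for each of these 5 genes. In edgeR's quasi-likelihood test the log2 changes, averaged over the sexes, were 2.90 ± 0.06 (SE) for Ifng (Benjamini-Hochberg adjusted p = 4.39e-21), 1.75 ± 0.06 for Il4 (adjusted p = 1.59e-17) and 7.38 ± 0.11 for Ccl1 (adjusted p = 7.1e-24). Of the 24 measured genes of the cytokine and chemokine list 19 rose, 3 fell and 2 did not pass (19 and 3 adjusted over the list alone, camera, adjusted p = 2.78e-17). Il10 had a mean of at most 0.615 CPM in every group. It passed toward higher levels for aGC in WT FT and KO FT mice and for the KO FT after aGC (edgeR, adjusted p = 0.00398, 9.85e-05 and 0.00387), and not in the other 5 comparisons (adjusted p = 1 each). Il17a did not pass the filter on low counts.

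The transcription factors that antigen receptor signals induce rose with the cytokines. Irf4 (ENSMUSG00000021356.10, chromosome 13, 30749226 to 30766976), needed for the growth of activated T cells, rose 9.06-fold, Irf8 11.7-fold, Egr2 3.36-fold and the NF-kappa-B regulator Nfkbid 4.80-fold. Of the 33 genes of this list 25 rose, 6 fell and 2 did not pass (25 and 6 adjusted over the list alone, camera, adjusted p = 5.59e-14). Among the activation and co-stimulatory receptors, Cd83 (ENSMUSG00000015396.4, chromosome 13, 43784775 to 43803132) rose 15.6-fold, Tnfrsf9, the gene of 4-1BB, 4.79-fold, Cd69 4.10-fold and Il2ra, the gene of the high-affinity interleukin 2 receptor chain, 3.52-fold. The list held 21 genes, of which 12 rose, 7 fell and 2 did not pass (13 and 7 adjusted over the list alone, camera, adjusted p = 2.09e-08). Genes of follicular helper-like iNKT cells rose as well, among them Cd200 (6.45-fold), the follicle homing receptor Cxcr5 (5.54-fold) and the inhibitory receptor gene Pdcd1 (2.33-fold). Of 13 list members 9 rose, 3 fell and 1 did not pass (9 and 3 adjusted over the list alone, camera, adjusted p = 0.00879). Of 16 markers of IL-10-producing and regulatory T cells 10 rose, 3 fell and 3 did not pass (10 and 3 adjusted over the list alone, camera, adjusted p = 0.0157). The pro-apoptotic gene Bcl2l11 rose 5.48-fold. Of 23 apoptosis and survival genes 11 rose, 8 fell and 4 did not pass (11 and 8 adjusted over the list alone, camera, adjusted p = 0.105). Eomes, a transcription factor of cytotoxic cells, had a log2 change of 3.39 ± 0.09. Of 17 cytotoxic effector genes 7 rose, 4 fell and 6 did not pass (7 and 4 adjusted over the list alone, camera, adjusted p = 0.0918).

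Genes of DNA replication, translation and energy metabolism rose in WT FT mice in both sexes. Mcm2, a subunit of the replicative helicase (ENSMUSG00000002870.8, chromosome 6, 88883474 to 88898780), went from 159.6 ± 1.66 to 597 ± 3.66 CPM in females and from 101 ± 3.73 to 581 ± 33.1 CPM in males, and Mcm3 rose 4.98-fold. Mki67, a marker of cycling cells, had low levels and a log2 change of 1.03 ± 0.22 (edgeR, adjusted p = 0.000203). Of 42 proliferation genes 36 rose, 2 fell and 4 did not pass (37 and 2 adjusted over the list alone, camera, adjusted p = 4.7e-29). The glycolysis genes Tpi1, Gapdh and Ldha rose 3.65-fold, 2.90-fold and 2.41-fold. Of 21 glycolysis genes 14 rose, 4 fell and 3 did not pass (14 and 4 adjusted over the list alone, camera, adjusted p = 3.39e-09). The ATP synthase gene Atp5b rose 2.11-fold. Of 44 nuclear genes of oxidative phosphorylation 41 rose, 0 fell and 3 did not pass (41 and 0 adjusted over the list alone, camera, adjusted p = 1.47e-11, 0.0997 with an estimated correlation). All 46 ribosomal protein genes rose (46 and 0 adjusted over the list alone, camera, adjusted p = 2.23e-17, 0.102 with an estimated correlation). Shorter genes tended to rise more (Spearman rho -0.188 with exon length). The amino acid transaminase gene Bcat1 stood at 2.42 and 0.301 CPM in females and males after PBS and at 91.5 and 102 after aGC. The chaperone genes Hsp90ab1 and Hspa5 rose 3.17-fold and 1.79-fold. Of 19 heat shock and dissociation stress genes 10 rose, 6 fell and 3 did not pass (10 and 6 adjusted over the list alone, camera, adjusted p = 1.01e-05). Of 22 unfolded protein response genes 16 rose, 4 fell and 2 did not pass (16 and 4 adjusted over the list alone, camera, adjusted p = 0.000727).

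Most markers of iNKT17 cells were lower with aGC in WT FT mice. The interleukin 7 receptor gene Il7r (ENSMUSG00000003882.5, chromosome 15, 9505788 to 9530176) had a log2 change of -1.81 ± 0.06 (edgeR, adjusted p = 7.59e-18), the chemokine receptor gene Cxcr3 of -1.17 ± 0.04, Ccr2 of -1.69 ± 0.07 and Il17rb, the receptor gene for interleukin 25, of -1.45 ± 0.04. The iNKT17 genes Nrp1, Ramp1 and Rora had log2 changes of -1.50, -1.24 and -0.90. Of 20 iNKT17 markers 3 rose, 16 fell and 1 did not pass (3 and 16 adjusted over the list alone, camera, adjusted p = 1.86e-07). Trav11, the variable segment of the invariant receptor, fell by 0.68 on the log2 scale. Of 28 genes of the TCR complex and its proximal signals 2 rose, 22 fell and 4 did not pass (2 and 22 adjusted over the list alone, camera, adjusted p = 6.93e-06, adjusted p = 0.143 with an estimated correlation). Zbtb16, the gene of the iNKT lineage factor PLZF, had a log2 change of -0.65 ± 0.06, Gata3 of -0.27 ± 0.07, Tbx21 of 0.12 ± 0.03 and Bcl6 of 0.54 ± 0.15 (edgeR, adjusted p = 1.74e-09, 0.00279, 0.00335 and 0.00293). Within the sexes Tbx21 changed by -0.28 in females and 0.52 in males (edgeR, adjusted p = 3.35e-05 and 2.01e-09). Of 24 iNKT1 markers 6 rose, 15 fell and 3 did not pass (6 and 15 adjusted over the list alone, camera, adjusted p = 0.0581), a list that passed when any 1 of 7 of the 24 libraries was left out. Of 18 iNKT2 markers 8 rose, 7 fell and 3 did not pass (8 and 7 adjusted over the list alone, camera, adjusted p = 0.68). Of 37 interferon-stimulated genes, with Ddx58, the gene of the RNA sensor RIG-I, at -1.38, 11 rose, 20 fell and 6 did not pass (11 and 20 adjusted over the list alone, camera, adjusted p = 0.375).

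Markers of naive T cells moved in opposite directions in the sexes. S1pr1, which lets T cells leave lymph nodes, had a log2 change of 0.62 in WT FT females and -3.39 in WT FT males. Cd8a (ENSMUSG00000053977.13, chromosome 6, 71373427 to 71379173), a co-receptor gene of conventional CD8 T cells, went from 6.30 ± 0.720 to 245 ± 6.05 CPM in females and from 287 ± 5.42 to 6.21 ± 0.682 in males. Averaged over the sexes, of 18 naive and lymph node recirculation genes 3 rose, 14 fell and 1 did not pass (3 and 14 adjusted over the list alone, camera, adjusted p = 2.61e-05). Of 9 conventional CD8 T cell markers 0 rose, 7 fell and 2 did not pass (0 and 7 adjusted over the list alone, camera, adjusted p = 0.033, adjusted p = 0.142 with an estimated correlation). Of 20 B cell markers 3 rose, 11 fell and 6 did not pass (3 and 11 adjusted over the list alone, camera, adjusted p = 0.0353, adjusted p = 0.0997 with an estimated correlation), with Ighm, the immunoglobulin mu gene, falling by 0.85 on the log2 scale. In all, 10908 of 15953 genes passed in WT FT mice, 4933 higher and 5975 lower. Among genes passing in each sex 19.5% had opposite signs. The naive and CD8 lists did not pass with 1 profile per group (camera, adjusted p = 0.118 and 0.241). In the fit on 1 profile per group 1618 genes passed, 1179 higher and 439 lower, and 4303 had an unadjusted p under 0.05. The female and the male responses were correlated at r = 0.604 across 8359 genes, which are not independent replicates.

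**Figure D2:**
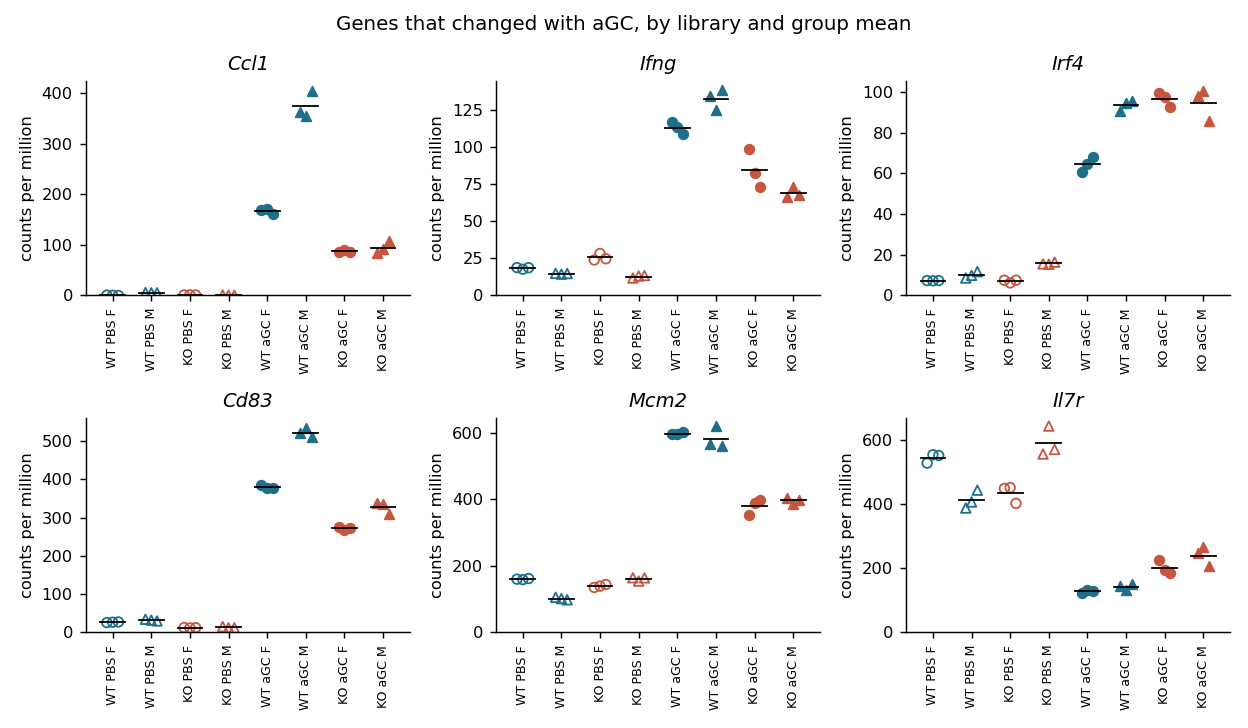
CPM of 6 genes in each library, by group (WT or KO FT, PBS or aGC, F female or M male), on a linear axis from 0. Symbols are single libraries and bars the mean of 3 libraries. Ifng, Ccl1, Irf4, Cd83 and Mcm2 are higher and Il7r is lower after aGC in all 4 pairs of groups.

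The same treatment was compared in KO FT mice, to read the response under the microbiota of donors without CD1d. There too the cytokine genes rose. Ifng went from 25.7 ± 2.34 to 85.0 ± 13.1 CPM in females and from 12.8 ± 0.877 to 69.0 ± 3.40 in males, a log2 change of 2.08 ± 0.06 (edgeR, adjusted p = 5.31e-18), and Il4 changed by 1.30 ± 0.06 (adjusted p = 1.08e-14). Ccl1, Ccl4 and Tnf rose 116-fold, 16.1-fold and 4.85-fold, and Tnfsf4, the gene of the co-stimulatory ligand OX40L, went from 0.396 and 0.287 CPM in females and males to 14.2 and 19.8. Of 24 cytokine and chemokine genes 19 rose, 3 fell and 2 did not pass (19 and 3 adjusted over the list alone, camera, adjusted p = 2.81e-24). Irf4, Irf8, Nr4a1 and Nfkbid rose 9.06-fold, 6.86-fold, 5.14-fold and 4.27-fold. Of 33 transcription factor genes 23 rose, 4 fell and 6 did not pass (23 and 4 adjusted over the list alone, camera, adjusted p = 2.73e-25). Cd83, Tnfrsf9, Cd69 and Il2ra rose 24.8-fold, 4.43-fold, 3.41-fold and 2.74-fold. Of 21 activation and co-stimulatory receptors 13 rose, 4 fell and 4 did not pass (13 and 5 adjusted over the list alone, camera, adjusted p = 8.65e-15). Of the follicular helper-like genes, Cd200 rose 4.44-fold and Cxcr5 3.53-fold. Of 13 members 9 rose, 2 fell and 2 did not pass (9 and 2 adjusted over the list alone, camera, adjusted p = 0.000162).

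The replication genes Mcm3 and Mcm5 rose 3.21-fold and 3.41-fold in KO FT mice. Of 42 proliferation genes 36 rose, 1 fell and 5 did not pass (37 and 1 adjusted over the list alone, camera, adjusted p = 2.98e-20). Mki67 had a log2 change of 0.37 ± 0.23 (edgeR, adjusted p = 0.174). The lactate transporter gene Slc16a1 and the glycolysis gene Tpi1 rose 3.45-fold and 2.60-fold. Of 21 glycolysis genes 14 rose, 2 fell and 5 did not pass (14 and 2 adjusted over the list alone, camera, adjusted p = 5.09e-08). Of 46 ribosomal protein genes 41 rose, 0 fell and 5 did not pass (41 and 0 adjusted over the list alone, camera, adjusted p = 1.71e-07, adjusted p = 0.328 with an estimated correlation). Of 44 oxidative phosphorylation genes 25 rose, 2 fell and 17 did not pass (25 and 2 adjusted over the list alone, camera, adjusted p = 0.00298, adjusted p = 0.475 with an estimated correlation), and their mean log2 CPM went from 7.54 to 7.49 in females and from 7.10 to 7.56 in males. Hsp90ab1 and Hspa8 rose 2.98-fold and 2.87-fold. Of 19 heat shock genes 13 rose, 3 fell and 3 did not pass (13 and 3 adjusted over the list alone, camera, adjusted p = 2.19e-14). Sterol synthesis genes rose in KO FT mice, with Sqle, the squalene epoxidase gene, 2.51-fold higher. Of 23 members 15 rose, 3 fell and 5 did not pass (15 and 3 adjusted over the list alone, camera, adjusted p = 0.00514). In WT FT mice Sqle rose 2.66-fold, and the list did not pass (camera, adjusted p = 0.0703). Of 16 co-inhibitory receptors 12 rose, 3 fell and 1 did not pass (12 and 3 adjusted over the list alone, camera, adjusted p = 0.00514).

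Il7r, Cxcr3, Il17rb, Ramp1, Rora and Emb fell, with log2 changes of -1.21, -0.90, -1.13, -1.11, -0.91 and -0.85. Of 20 iNKT17 markers 1 rose, 16 fell and 3 did not pass (1 and 16 adjusted over the list alone, camera, adjusted p = 1.68e-09). Of 24 iNKT1 markers 3 rose, 13 fell and 8 did not pass (3 and 13 adjusted over the list alone, camera, adjusted p = 0.0225), and their mean log2 CPM went from 6.59 to 5.89 in females and from 5.81 to 6.03 in males. Zbtb16 had a log2 change of -0.49 ± 0.06 (edgeR, adjusted p = 3.07e-07), with 3 of 6 aGC libraries below all PBS ones and a rise of 0.26 without PBS males and aGC females, Bcl6 of 0.85 ± 0.15 (adjusted p = 3.8e-05), and Tbx21 and Gata3 of -0.02 ± 0.03 and 0.06 ± 0.07 (adjusted p = 0.606 and 0.51). The mean log2 CPM of the interferon-stimulated genes went from 6.56 to 5.34 in females and from 5.58 to 5.86 in males, while 16 of the 37 were lower and 5 higher in both sexes. Ifit3, an antiviral effector gene (ENSMUSG00000074896.3, chromosome 19, 34583531 to 34588731), went from 387 ± 10.5 to 31.9 ± 3.76 CPM in females, while the male values were 95.4 ± 3.92 and 112 ± 14.0. Ifit1 changed by -2.96 in females and 0.53 in males (-1.22 on average). Irf7, the gene of an interferon response factor, was lower with aGC in all 6 libraries (log2 change -1.05 ± 0.04). Averaged over the sexes, of 37 interferon-stimulated genes 7 rose, 24 fell and 6 did not pass (7 and 24 adjusted over the list alone, camera, adjusted p = 4.6e-07). Cd8a moved with the naive genes as in WT FT mice, from 5.20 ± 0.424 to 189 ± 9.31 CPM in females and from 136 ± 4.60 to 7.59 ± 0.469 in males. Of 18 naive genes 2 rose, 10 fell and 6 did not pass (2 and 10 adjusted over the list alone, camera, adjusted p = 0.000961), a list that did not pass with 1 profile per group (camera, adjusted p = 0.22). In all, 9273 genes passed, 4477 higher and 4796 lower. Among genes passing in each sex 26% had opposite signs, and the sexes correlated at r = 0.478. A fit on 1 profile per group called 331 genes, 306 higher and 25 lower, and 2695 had an unadjusted p under 0.05. Of the genes higher with aGC, 3205 were shared by both FT groups (1384 by chance), and of the genes lower 3393 (1796 by chance), while 312 and 449 passed in opposite directions (1483 and 1677 by chance). The responses of the FT groups were correlated at r = 0.632 in females and 0.826 in males.

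Whether the response to antigen differed with the donor was tested as the difference between the KO FT and the WT FT response. The rise of replication, ribosomal and oxidative phosphorylation genes was smaller in KO FT mice. Cdc6, which loads the replicative helicase, rose from 9.20 to 39.7 CPM in WT FT females and from 9.23 to 20.7 in KO FT females, and in males from 1.67 to 67.3 and from 9.07 to 31.4. The differences between the log2 responses were -2.23 ± 0.12 for Cdc6 (edgeR, adjusted p = 1.37e-11), -0.83 ± 0.05 for Mcm2 (adjusted p = 2.77e-11), -1.89 ± 0.11 for Rrm2, a subunit of ribonucleotide reductase (adjusted p = 3.89e-11), and -0.78 ± 0.06 for the tubulin regulator Stmn1 (adjusted p = 7.36e-10). Of 42 proliferation genes 2 were higher, 27 were lower and 13 did not pass (2 and 28 adjusted over the list alone, camera, adjusted p = 4.83e-14). The ribosomal gene Rpl4 (-0.36), the respiratory gene Cyc1 (-0.57) and the glycolysis gene Pkm (-0.58) had smaller rises too. Of 46 ribosomal protein genes 0 were higher, 44 were lower and 2 did not pass (0 and 45 adjusted over the list alone, camera, adjusted p = 1.54e-15, adjusted p = 0.248 with an estimated correlation). Of 44 oxidative phosphorylation genes 0 were higher, 41 were lower and 3 did not pass (0 and 41 adjusted over the list alone, camera, adjusted p = 5e-15, adjusted p = 0.192 with an estimated correlation). Of 21 glycolysis genes 4 were higher, 12 were lower and 5 did not pass (4 and 13 adjusted over the list alone, camera, adjusted p = 0.00391, adjusted p = 0.259 with an estimated correlation). Of 20 B cell markers 7 were higher, 1 was lower and 12 did not pass (7 and 1 adjusted over the list alone, camera, adjusted p = 0.0371, adjusted p = 0.239 with an estimated correlation), and of 22 genes of the unfolded protein response 2 were higher, 11 were lower and 9 did not pass (2 and 12 adjusted over the list alone, camera, adjusted p = 0.0308, adjusted p = 0.248 with an estimated correlation). Neither of the last 2 lists passed with 1 profile per group (camera, adjusted p = 0.251 and 0.326). Gene length moved with this comparison (Spearman rho 0.368 across 8359 genes), and with an offset for that trend the median of the proliferation genes went from -0.61 to -0.60, of the ribosomal genes from -0.49 to -0.27 and of the oxidative phosphorylation genes from -0.43 to -0.21.

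Ifng and Il4 had smaller rises in KO FT mice, with differences of -0.82 ± 0.09 (edgeR, adjusted p = 1.77e-07) and -0.46 ± 0.09 (adjusted p = 0.000151), as had Irf8 (-0.77), Bhlhe40 (-0.88) and Tnfrsf18, the gene of the co-stimulatory receptor GITR (-0.61). Larger in KO FT mice were the responses of Cd83 (0.67), Nfatc1 (0.76), Plcg1 (0.97) and, in females only, the gut homing receptor gene Ccr9 (0.58 on average), and Il7r fell less (0.60). Of 24 cytokine and chemokine genes 4 were higher, 5 were lower and 15 did not pass (4 and 5 adjusted over the list alone, camera, adjusted p = 0.538). Of 18 naive genes 11 were higher, 2 were lower and 5 did not pass (11 and 2 adjusted over the list alone, camera, adjusted p = 0.00759), in males, where their mean log2 CPM fell from 7.42 to 5.32 in WT FT and from 7.14 to 5.62 in KO FT mice. The mean response of the interferon-stimulated genes was lower in KO FT than in WT FT females and higher in KO FT males. Their mean log2 CPM went from 6.00 to 6.04 in WT FT and from 6.56 to 5.34 in KO FT females. In males it went from 5.47 to 5.18 and from 5.58 to 5.86. The naive list did not pass with 1 profile per group (camera, adjusted p = 0.57). Averaged over the sexes Ifit3 differed by -1.57, and of 37 members 5 were higher, 22 were lower and 10 did not pass (6 and 24 adjusted over the list alone, camera, adjusted p = 4.83e-07). The differences of Tbx21 and Gata3 were -0.14 ± 0.05 and 0.33 ± 0.11 (edgeR, adjusted p = 0.0193 and 0.0137), and those of Zbtb16, Bcl6 and Mki67 0.17 ± 0.09, 0.31 ± 0.21 and -0.67 ± 0.31 (adjusted p = 0.125, 0.253 and 0.09). Leaving out 1 library decided 2 of these calls. Mki67 passed without WT FT aGC female replicate 2, KO FT PBS male replicate 3 or KO FT aGC female replicate 3 (-0.78, -0.77 and -0.97), and Zbtb16 passed without KO FT aGC male replicate 2 (0.21). In all, 7093 genes passed, 3492 higher and 3601 lower. On 1 profile per group edgeR called 0 genes, with 628 at an unadjusted p under 0.05.

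What the donor of the microbiota changed without antigen was read from KO FT against WT FT after PBS. Interferon-stimulated genes were higher in KO FT mice of both sexes. Ifit3 stood at 116 ± 2.24 CPM in WT FT and 387 ± 10.5 in KO FT females, and at 59.0 ± 0.491 and 95.4 ± 3.92 in males, a log2 difference of 1.22 ± 0.05 (edgeR, adjusted p = 1.48e-13). Ifit1 differed by 0.66 ± 0.04 (adjusted p = 2.31e-10) and the interferon-induced chemokine gene Cxcl10 by 1.40 ± 0.13 (adjusted p = 8.66e-08), from 7.69 to 11.4 CPM in females and from 0.482 to 2.29 in males. For each of these 3 genes 3 of the 6 KO FT libraries lay above all 6 WT FT ones. Of 37 interferon-stimulated genes 22 were higher, 1 was lower and 14 did not pass (26 and 1 adjusted over the list alone, camera, adjusted p = 1.09e-16), and 26 of the 37 were higher and 0 lower in both sexes. With 1 profile per group this list passed, as did the B cell and heat shock lists (camera, adjusted p = 2.27e-05, 1.51e-05 and 0.0472). The iNKT17, iNKT1, naive, and macrophage and dendritic cell lists did not (adjusted p = 0.0547, 0.284, 0.657 and 0.376). These p-values rest on the preset correlation between genes and do not measure how a list varies between cell pools. Of 20 iNKT17 markers 10 were higher, 1 was lower and 9 did not pass (12 and 1 adjusted over the list alone, camera, adjusted p = 0.000351), with Il23r, the interleukin 23 receptor gene, at 0.87 ± 0.12 and Rora at 0.23 ± 0.03 on the log2 scale. Of 24 iNKT1 markers, with a mean log2 CPM of 6.36 in WT FT and 6.59 in KO FT females and of 5.95 and 5.81 in males, 8 were higher, 2 were lower and 14 did not pass (9 and 3 adjusted over the list alone, camera, adjusted p = 0.0263, adjusted p = 0.0687 with an estimated correlation), whose mean of -0.03 and median of 0.09 differed in sign.

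Cd83 was lower in KO FT mice, at 11.6 ± 0.515 against 25.9 ± 0.848 CPM in females and 12.5 ± 1.73 against 31.5 ± 2.21 in males. All 6 KO FT libraries lay below all 6 WT FT ones. For Tnfrsf4, the gene of the co-stimulatory receptor OX40, 3 of 6 did (log2 difference -0.79 ± 0.09, edgeR, adjusted p = 1.15e-06). The antigen presentation genes Cd74 and H2-Ab1, which the B cell list holds, differed by -0.88 ± 0.05 and -0.97 ± 0.08. Of 20 B cell markers 1 was higher, 12 were lower and 7 did not pass (1 and 12 adjusted over the list alone, camera, adjusted p = 8.99e-11). The male difference in Cd74 was -1.71 and the female -0.06. Lyz2, the lysozyme gene of myeloid cells, had 21.4 CPM in WT FT and 0.473 in KO FT males. Of 25 macrophage and dendritic cell markers 2 were higher, 7 were lower and 16 did not pass (2 and 7 adjusted over the list alone, camera, adjusted p = 0.0263, adjusted p = 0.0735 with an estimated correlation), a fall in males, whose mean log2 CPM was 1.79 in WT FT and 1.13 in KO FT mice, against 1.95 and 1.96 in females. Hspa8 had a log2 difference of -0.33, with 0 of 6 KO FT libraries below all WT FT ones. Of 19 heat shock genes 2 were higher, 10 were lower and 7 did not pass (2 and 13 adjusted over the list alone, camera, adjusted p = 0.000751). The naive gene Klf2 was lower (-0.32). Of 18 naive genes 2 were higher, 8 were lower and 8 did not pass (2 and 10 adjusted over the list alone, camera, adjusted p = 0.00849), beside a Cd8a level of 287 CPM in WT FT and 136 CPM in KO FT males. The co-inhibitory receptor, CD8 and X-linked lists passed toward lower levels (camera, adjusted p = 0.0263, 0.0243 and 0.0263, and 0.0735, 0.149 and 0.25 with an estimated correlation). Ifng and Il4 did not pass, with 0.14 ± 0.07 and 0.12 ± 0.06 (edgeR, adjusted p = 0.134 and 0.171), nor did Gata3, Bcl6 and Mki67, with -0.15, 0.02 and -0.01, while Tbx21 and Zbtb16 were higher by 0.17 and 0.22, the latter in males only (0.49, against -0.05 in females). In all, 4690 genes passed, 2323 higher and 2367 lower in KO FT mice, of which 3240 (69.1%) had the same sign in both sexes. Of the 2423 genes that passed in each sex, 658 had the same direction and 1765 (72.8%) opposite directions, and r between the sexes was -0.254. With the B cell marker level as a covariate 3 genes passed in edgeR, and 1346 had an unadjusted p under 0.05. Of the sum of squares of that level 97.7% lay between the 8 groups. Fitted to 1 profile per group, edgeR called 0 genes, with 255 at an unadjusted p under 0.05.

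After aGC, KO FT mice had lower proliferation, ribosomal and oxidative phosphorylation genes than WT FT mice in both sexes. Mcm2 stood at 380.0 ± 23.0 CPM in KO FT and 597 ± 3.66 in WT FT females and at 397 ± 9.36 and 581 ± 33.1 in males, and Stmn1 at 78.4 and 155 CPM in females and 124 and 197 in males. For these genes and for Mcm3, Tyms, Cyc1, Sdhb, Rpl4, Pkm and Gapdh all 6 KO FT libraries lay below all 6 WT FT libraries. In edgeR's quasi-likelihood test the log2 differences were -0.60 ± 0.03 for Mcm2 (adjusted p = 3.23e-12), -0.61 ± 0.04 for Mcm3 (adjusted p = 9.19e-12), -0.83 ± 0.04 for Stmn1 (adjusted p = 2.16e-13) and -1.08 ± 0.07 for Tyms, which makes thymidylate (adjusted p = 1.76e-11). Mki67 differed by -0.68 ± 0.22 (edgeR, adjusted p = 0.013). Of 42 proliferation genes 1 was higher, 34 were lower and 7 did not pass (1 and 34 adjusted over the list alone, camera, adjusted p = 2.63e-17). The differences of Cyc1, Sdhb, Rpl4, Pkm and Gapdh were -0.57, -0.46, -0.37, -0.52 and -0.49. Of 44 oxidative phosphorylation genes 0 were higher, 44 were lower and 0 did not pass (0 and 44 adjusted over the list alone, camera, adjusted p = 4.81e-18, adjusted p = 0.105 with an estimated correlation). Of 46 ribosomal protein genes 0 were higher, 45 were lower and 1 did not pass (0 and 46 adjusted over the list alone, camera, adjusted p = 1.68e-16, adjusted p = 0.253 with an estimated correlation). Of 21 glycolysis genes 4 were higher, 13 were lower and 4 did not pass (4 and 13 adjusted over the list alone, camera, adjusted p = 0.00802, adjusted p = 0.363 with an estimated correlation). Gene length moved with this comparison, since the log2 differences correlated with exon length at a Spearman rho of 0.419 across 8359 genes. With an offset for that trend the median over the 132 members of the 3 lists went from -0.43 to -0.28, and that of the proliferation genes from -0.62 to -0.61.

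Ifng, Il4 and some other genes of effector cells were lower in KO FT mice after aGC. Ifng stood at 85.0 ± 13.1 against 113 ± 4.20 CPM in females and 69.0 ± 3.40 against 133 ± 6.68 in males, a difference of -0.68 ± 0.06 (edgeR, adjusted p = 1.83e-09), and Il4 differed by -0.34 ± 0.06 (adjusted p = 3.95e-05). Ccl1, Ccl4 and Irf8 differed by -1.46, -0.61 and -0.42, Tnfrsf4 (ENSMUSG00000029075.6, chromosome 4, 156013843 to 156016612) by -1.24, Tnfrsf18 by -0.50 and Cd200 by -0.56. Of 24 cytokine and chemokine genes 2 were higher, 10 were lower and 12 did not pass (2 and 10 adjusted over the list alone, camera, adjusted p = 0.046, adjusted p = 0.253 with an estimated correlation), which failed without KO FT aGC male replicate 1 or 2 (adjusted p = 0.0615 and 0.0543) and with 1 profile per group (0.29), as did the glycolysis list (0.0565). Of 21 activation and co-stimulatory receptors 7 were higher, 8 were lower and 6 did not pass (7 and 8 adjusted over the list alone, camera, adjusted p = 0.761). Genes higher in KO FT mice were Il7r (0.70), Ccr2 (0.85), Ccr9 (0.67), the ATP receptor gene P2rx7 (0.49), Il17rb (0.59), the glycerol channel gene Aqp3 (0.87), the kinase gene Blk (1.08) and Cd44 (0.57), for Il17rb and Blk with 3 of 6 KO FT libraries above all WT FT ones and for the others with 6. Of 22 tissue residency and gut homing genes 15 were higher, 4 were lower and 3 did not pass (15 and 4 adjusted over the list alone, camera, adjusted p = 0.000562, adjusted p = 0.0618 with an estimated correlation). Of 20 iNKT17 markers 13 were higher, 0 were lower and 7 did not pass (13 and 2 adjusted over the list alone, camera, adjusted p = 0.00103, adjusted p = 0.0618 with an estimated correlation). The signalling gene Plcg1 was higher by 1.12. Of 28 genes of the TCR complex and its signals 11 were higher, 8 were lower and 9 did not pass (11 and 8 adjusted over the list alone, camera, adjusted p = 0.356). Zbtb16, in males only (0.80, against -0.02 in females), and Gata3 differed by 0.39 ± 0.06 and 0.18 ± 0.07 (edgeR, adjusted p = 1.78e-05 and 0.0461), and Tbx21 and Bcl6 by 0.03 ± 0.03 and 0.33 ± 0.15 (adjusted p = 0.521 and 0.0668). Gata3 failed when any 1 of 17 of the 24 libraries was left out, and Bcl6 passed without WT FT aGC female replicate 2, WT FT aGC male replicate 1 or KO FT aGC male replicate 2 (0.41, 0.40 and 0.41). Ctse, the cathepsin E gene, had 259.7 ± 21.2 CPM in KO FT males, against 11.2 in WT FT males, 20.2 in KO FT females and 21.4 in WT FT females. The interferon-stimulated genes split by sex, with Ifit3 at -2.07 in females and 1.36 in males. Of 37 members 11 were higher, 20 were lower and 6 did not pass (11 and 21 adjusted over the list alone, camera, adjusted p = 0.624). In all, 8278 genes passed, 4049 higher and 4229 lower. Among genes passing in each sex 17.4% had opposite signs (r = 0.477). On 1 profile per group edgeR called 0 genes, with 1306 at an unadjusted p under 0.05.

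**Figure D3:**
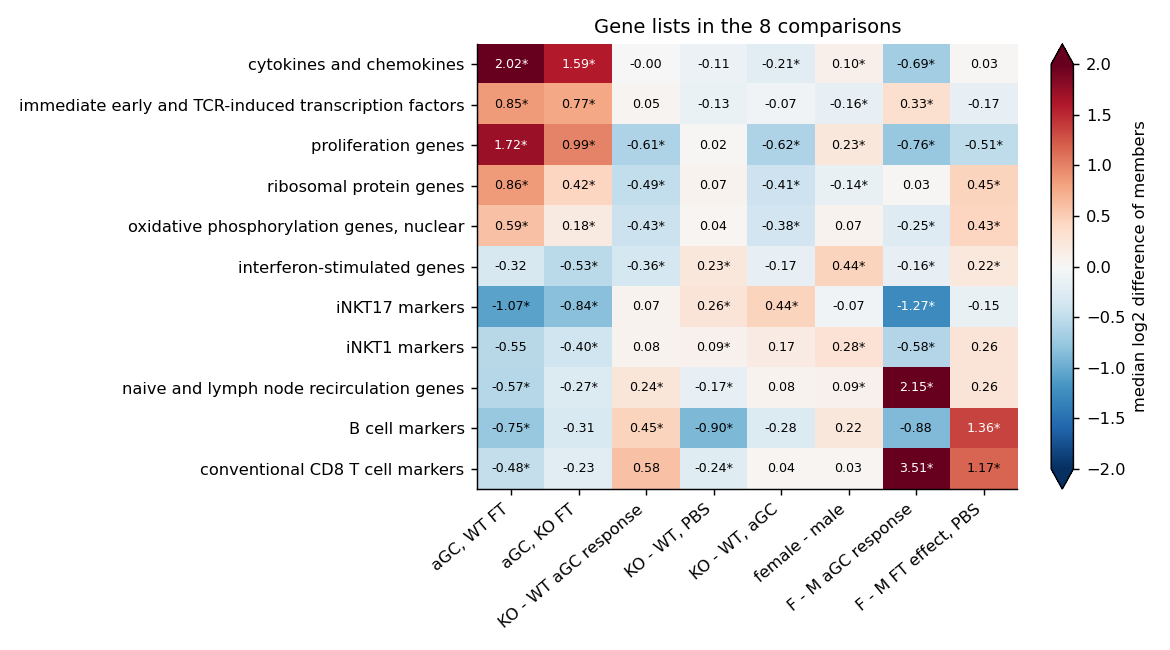
Median log2 difference of the measured members of 11 gene lists (vertical axis) in the 8 comparisons (horizontal axis, F female and M male), with the value in each cell and a colour scale that ends at 2 and -2. An asterisk marks an adjusted p under 0.05 in camera with a preset correlation. The largest medians are those of the CD8 and naive lists in the difference between the female and the male aGC response.

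Sex was compared as females against males over the 4 combinations of FT and treatment. The mean of the interferon-stimulated genes was higher in females in 3 of these combinations and lower in KO FT mice after aGC. Their mean log2 CPM in females and males was 6.00 and 5.47 in WT FT mice after PBS, 6.04 and 5.18 after aGC, 6.56 and 5.58 in KO FT mice after PBS, and 5.34 and 5.86 after aGC. The GTPase gene Igtp had 688 and 453 CPM in WT FT females and males after PBS, and 907 and 576 after aGC, and its 12 female libraries lay above all 12 male ones, as did those of the GTPase gene Gbp4. The log2 differences, averaged over the combinations, were 0.69 ± 0.03 for Usp18 (edgeR, adjusted p = 1.38e-14), 0.49 ± 0.02 for Igtp (adjusted p = 2.14e-14), 0.54 ± 0.02 for Gbp4 (adjusted p = 8.3e-14) and 1.51 ± 0.08 for Cxcl10 (adjusted p = 3.59e-12). Of 37 interferon-stimulated genes 33 were higher, 0 were lower and 4 did not pass (34 and 0 adjusted over the list alone, camera, adjusted p = 7.59e-57), and the list passed with 1 profile per group (camera, adjusted p = 2.05e-20). In KO FT mice after aGC Ifit3, Usp18 and Cxcl10 were lower in females than in males, at 31.9 and 112, 30.4 and 70.8, and 10.1 and 13.7 CPM. Of 24 iNKT1 markers 17 were higher, 2 were lower and 5 did not pass (17 and 2 adjusted over the list alone, camera, adjusted p = 1.98e-08), among them Tbx21 (0.38 ± 0.02, edgeR, adjusted p = 5.45e-11), Txk (0.31), the NKG2D gene Klrk1 (0.38) and Ifng (0.35). Their mean log2 CPM in females and males was 6.36 and 5.95 (WT FT) and 6.59 and 5.81 (KO FT) after PBS. After aGC it was 5.80 and 6.00, and 5.89 and 6.03. The Cd8a-high sex was lower in all 4 pairs. Ifng was lower in WT FT females than males after aGC. Of 18 iNKT2 markers 3 were higher, 7 were lower and 8 did not pass (3 and 7 adjusted over the list alone, camera, adjusted p = 0.00534), with Zbtb16 at -0.40, although the list mean was higher in WT FT females (6.62) than males (6.48) after aGC.

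After PBS proliferation and unfolded protein response genes were lower in the Cd8a-high males. The mean log2 CPM of the proliferation genes was 3.83 in females and 2.70 in males of the WT FT and 3.56 and 3.12 of the KO FT. After aGC it was lower in females, at 4.95 and 5.03, and 4.17 and 4.51. For the unfolded protein response it was 7.21 and 6.94, and 7.20 and 6.96, after PBS and 7.42 and 7.48, and 7.33 and 7.30, after aGC. Averaged over FT and treatment, of 42 proliferation genes 27 were higher, 3 were lower and 12 did not pass (28 and 6 adjusted over the list alone, camera, adjusted p = 1.92e-05), although Mki67 was lower (-0.43), a call that failed when any 1 of 14 of the 24 libraries was left out. Of 22 genes of the unfolded protein response, with Hspa5 at 0.24, 14 were higher, 2 were lower and 6 did not pass (15 and 2 adjusted over the list alone, camera, adjusted p = 6.2e-05). The immediate early genes Egr1, Fos and Egr2 were lower in females on average, at -0.29, -0.63 and -0.34, from the PBS groups, with Cd8a-high males. The mean log2 CPM of their list was 4.97 in females and 5.44 in males of the WT FT after PBS and 6.18 and 6.20 after aGC, and 4.85 and 5.31, and 6.13 and 6.12, in KO FT mice. Of 33 members 3 were higher, 19 were lower and 11 did not pass (3 and 20 adjusted over the list alone, camera, adjusted p = 1.37e-08). Of 46 ribosomal protein genes, with Rpl4 at -0.12, 0 were higher, 32 were lower and 14 did not pass (0 and 37 adjusted over the list alone, camera, adjusted p = 6.46e-09, adjusted p = 0.339 with an estimated correlation), although in KO FT mice after PBS the list mean was higher in females (7.74) than in males (7.66). The X-linked genes Eif2s3x and Kdm6a, which escape X inactivation, were higher in females by 0.58 and 0.87. Of 14 X-linked genes 9 were higher, 2 were lower and 3 did not pass (9 and 3 adjusted over the list alone, camera, adjusted p = 1.7e-10). All 4 measured Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, were lower in females (0 higher and 4 lower adjusted over the list alone, camera, adjusted p = 9.29e-207). The naive and cytokine lists passed toward higher and the mitochondrially encoded genes toward lower levels in females (camera, adjusted p = 0.0221, 0.0495 and 0.0495). With an estimated correlation the last 2 did not pass (adjusted p = 0.257 and 0.466). Il4, Gata3 and Bcl6 did not pass, with 0.07, 0.01 and 0.08, nor did Cd8a (-0.08), which was higher in males after PBS and in females after aGC. Il4 passed without KO FT PBS male replicate 2 (0.11). In all, 6024 genes passed, 3309 higher and 2715 lower in females. With 1 profile per group the iNKT2 and unfolded protein response lists did not pass (camera, adjusted p = 0.3 and 0.0522). Among the summed profiles 5 genes passed, Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and 425 had an unadjusted p under 0.05.

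Whether females and males answered antigen differently was tested as the difference between their aGC responses, averaged over the FT groups. Markers of conventional CD8 T cells and of naive cells rose in females and fell in males. Cd8b1 went from 9.83 ± 0.663 to 390.2 ± 5.17 CPM in WT FT females and from 573 ± 1.08 to 12.3 ± 0.590 in WT FT males. The differences between the log2 responses were 10.46 ± 0.05 for Cd8b1 (edgeR, adjusted p = 9.96e-34), 10.10 ± 0.08 for Cd8a (adjusted p = 8.37e-30) and 4.78, 3.52 and 2.46 for Klf2, S1pr1 and Ccr7. Of 9 CD8 markers 9 were higher, 0 were lower and 0 did not pass (9 and 0 adjusted over the list alone, camera, adjusted p = 4.9e-122). Of 18 naive genes 17 were higher, 0 were lower and 1 did not pass (17 and 1 adjusted over the list alone, camera, adjusted p = 6.87e-113). The invariant segments Trav11 and Traj18 had lower responses in females (-0.90 and -0.85), while Jun, Fos and Egr1 had higher ones (2.91, 2.83 and 1.05). Of 33 transcription factor genes 17 were higher, 8 were lower and 8 did not pass (17 and 8 adjusted over the list alone, camera, adjusted p = 8.25e-07, adjusted p = 0.0606 with an estimated correlation). Of 19 heat shock and dissociation stress genes, a list that also holds Jun and Fos, 8 were higher, 5 were lower and 6 did not pass (8 and 5 adjusted over the list alone, camera, adjusted p = 8.5e-08), and their median of -0.02 and mean of 0.60 differed in sign.

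Cytokine genes and iNKT1 and iNKT17 markers had lower responses in females, beside the shift in CD8 markers. The differences were -1.39 ± 0.09 for Il4 (edgeR, adjusted p = 5.24e-12), -0.63 for Ifng, -1.25 for Ccl4, -0.76 for Tbx21, -1.01 for Rora, -1.37 for Id2, -1.70 for the tissue homing receptor gene Cxcr6, -0.57 for Gata3 and -0.44 for Zbtb16. Eomes had a higher response in females (3.24), and Bcl6 did not pass (0.42, edgeR, adjusted p = 0.105), except without KO FT aGC male replicate 1 (0.54). Of 24 cytokine and chemokine genes 2 were higher, 15 lower and 7 did not pass (2 and 15 adjusted over the list alone, camera, adjusted p = 0.000144). Of 24 iNKT1 markers 1 was higher, 18 lower and 5 did not pass (1 and 18 adjusted over the list alone, camera, adjusted p = 1.17e-07). Of 20 iNKT17 markers 0 were higher, 16 lower and 4 did not pass (0 and 16 adjusted over the list alone, camera, adjusted p = 1.12e-09). Of 18 iNKT2 markers 9 were higher, 7 lower and 2 did not pass (9 and 7 adjusted over the list alone, camera, adjusted p = 0.000174), toward larger responses in females, unlike those of Il4, Gata3 and Zbtb16. The proliferation genes Stmn1, Rrm2 and Mki67 differed by -1.31, -1.78 and -1.72. Of 42 members 3 were higher, 31 were lower and 8 did not pass (4 and 31 adjusted over the list alone, camera, adjusted p = 1.06e-07). Ifit1 differed by -1.83. Of 37 interferon-stimulated genes 5 were higher, 20 were lower and 12 did not pass (5 and 21 adjusted over the list alone, camera, adjusted p = 3.59e-05), while in WT FT mice their mean log2 CPM went from 6.00 to 6.04 in females and from 5.47 to 5.18 in males. Of 44 oxidative phosphorylation genes 1 was higher, 30 lower and 13 did not pass (2 and 31 adjusted over the list alone, camera, adjusted p = 3.59e-05, 0.434 with an estimated correlation), and the mitochondrially encoded genes passed too (camera, adjusted p = 0.0413, 0.6 with an estimated correlation). Hspa5 differed by -0.67. Of 22 genes of the unfolded protein response 4 were higher, 17 were lower and 1 did not pass (4 and 17 adjusted over the list alone, camera, adjusted p = 8.5e-08). Lyz2 went from 0.473 to 26.5 CPM in KO FT males and from 36.4 to 7.23 in KO FT females. Of 25 macrophage and dendritic cell markers 4 were higher, 14 were lower and 7 did not pass (5 and 15 adjusted over the list alone, camera, adjusted p = 0.00237). In all, 8169 genes passed, 3846 higher and 4323 lower. With 1 profile per group and a term for sex by treatment 94 genes passed, 86 higher and 8 lower, and 1964 had an unadjusted p under 0.05.

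**Figure D4:**
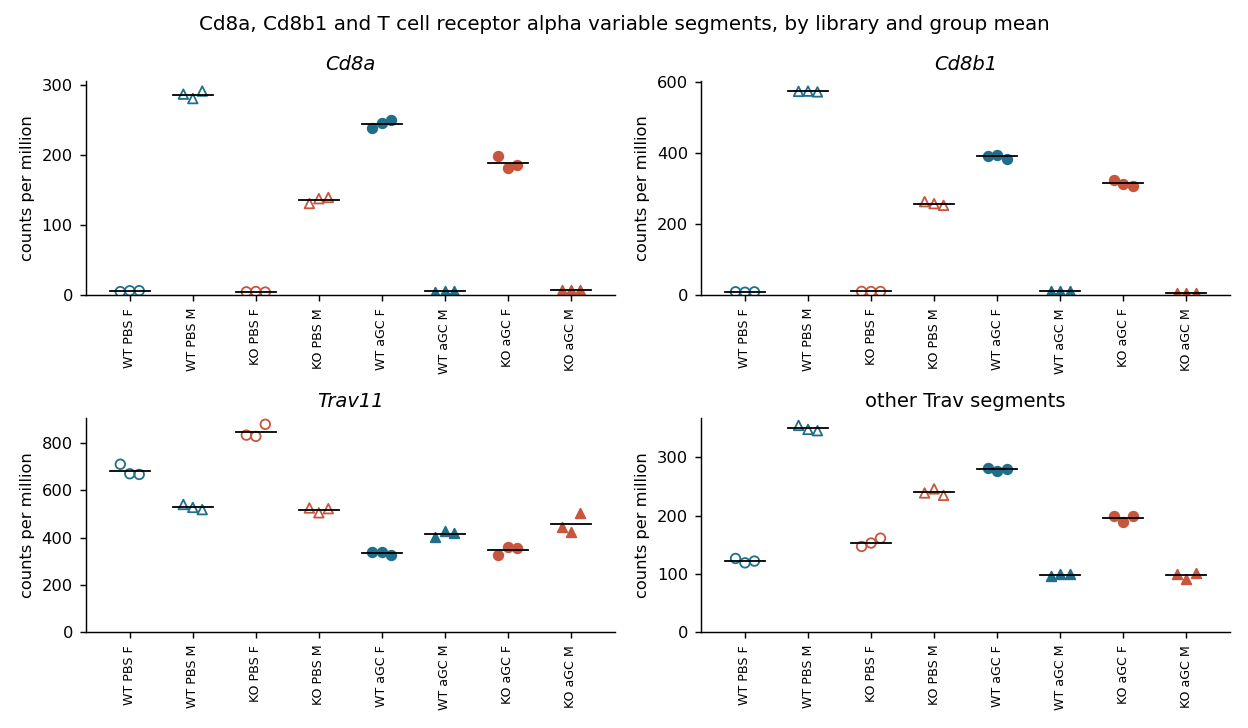
CPM of Cd8a, Cd8b1, Trav11 and the sum of the other T cell receptor alpha variable (Trav) segments in each library, by group (WT or KO FT, PBS or aGC, F female or M male), on a linear axis from 0. Symbols are single libraries and bars the mean of 3. Cd8a, Cd8b1 and the other segments are higher in males than in females after PBS and higher in females after aGC, in both FT groups.

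The last comparison asked whether the donor effect after PBS differed between females and males, as the female minus the male difference between KO FT and WT FT. Markers of B cells were lower in KO FT males and less so in KO FT females, and those of macrophages and dendritic cells were lower in KO FT males, with nearly equal means in females. Cd74 stood at 96.6 CPM in WT FT and 29.9 in KO FT males and at 85.6 and 81.9 in females, a difference of 1.64 ± 0.10 (edgeR, adjusted p = 1.13e-10), and H2-Ab1 differed by 1.31. Lyz2 stood at 21.4 and 0.473 CPM in males and at 61.0 and 36.4 in females. Of 20 B cell markers 13 were higher, 1 lower and 6 did not pass (14 and 1 adjusted over the list alone, camera, adjusted p = 7.92e-06). Of 25 macrophage and dendritic cell markers 11 were higher, 3 lower and 11 did not pass (11 and 3 adjusted over the list alone, camera, adjusted p = 0.0351, 0.214 with an estimated correlation), a list that failed without WT FT PBS male replicate 2, KO FT PBS female replicate 3 or KO FT PBS male replicate 2 (adjusted p = 0.0518, 0.0539 and 0.0938). The donor effect on the interferon-stimulated genes Usp18 and Ifit3 was higher in females, by 1.69 ± 0.08 (edgeR, adjusted p = 1.39e-12) and 1.04 ± 0.10 (adjusted p = 8.01e-08). Of 37 members 15 were higher, 2 were lower and 20 did not pass (16 and 3 adjusted over the list alone, camera, adjusted p = 0.000294). The donor effect on Cdc6 and Mcm2 was higher in males, with differences of -2.41 and -0.86. Of 42 proliferation genes 2 were higher, 20 were lower and 20 did not pass (3 and 23 adjusted over the list alone, camera, adjusted p = 8.41e-05, adjusted p = 0.1 with an estimated correlation). Il17rb and Ccr9 were lower in KO FT females and higher in KO FT males, with differences of -1.35 and -1.36. Of 46 ribosomal protein genes, with Rpl4 at 0.33, 38 were higher, 0 were lower and 8 did not pass (39 and 0 adjusted over the list alone, camera, adjusted p = 3.01e-09, adjusted p = 0.383 with an estimated correlation). Of 44 oxidative phosphorylation genes 35 were higher, 1 was lower and 8 did not pass (37 and 1 adjusted over the list alone, camera, adjusted p = 3.25e-08, adjusted p = 0.286 with an estimated correlation). Cd8b1 moved with these groups, by 1.33. Of 9 CD8 markers 6 were higher, 1 was lower and 2 did not pass (6 and 2 adjusted over the list alone, camera, adjusted p = 0.0227, adjusted p = 0.284 with an estimated correlation). Ifng and Zbtb16 differed by 0.67 ± 0.14 and -0.54 ± 0.12 (edgeR, adjusted p = 0.000371 and 0.000793), and Il4, Tbx21, Gata3, Bcl6 and Mki67 did not pass, with -0.21, -0.05, -0.07, 0.06 and -0.09. In all, 6831 genes passed, 3468 higher and 3363 lower. With the B cell marker level as a covariate 167 genes passed. On summed profiles with a term for sex by FT, which averages over PBS and aGC, edgeR called 0 genes, with 202 at an unadjusted p under 0.05. In that fit the ribosomal, oxidative phosphorylation and proliferation lists passed in the same direction, the interferon-stimulated list passed in the opposite one (camera, adjusted p = 7.07e-05), and the B cell (0.0966), macrophage (0.702) and CD8 (0.513) lists did not pass.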

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

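The tests of mislabelled groups, of a sex difference in the aGC response, of the share of CD8 T cells and of an FT effect against single cell pools, the length test of the proliferation genes alone and the fits with 1 profile per group were chosen after results were seen. A test of the difference itself marked 3 comparisons: 7093 genes had a different aGC response in KO FT than in WT FT mice, 8169 in females than in males, and 6831 had a different FT effect in females than in males after PBS. The same test marked Cd8b1 and Cd8a, whose aGC responses differed between females and males by 10.46 and 10.10 on the log2 scale. When labels were shuffled within the strata of a comparison, 100 splits including the real one were counted. The real split of aGC in WT FT mice called 10908 genes and the highest other split 7695, for KO FT mice 9273 and 5639, and for the difference between these responses 7093 and 3256. For KO FT against WT FT the values were 4690 and 3611 after PBS and 8278 and 4756 after aGC, for the aGC response by sex 8169 and 4128, and for the FT effect by sex 6831 and 3796. In these 7 comparisons 1 of the 100 splits, the real one, called as many genes. For sex the real split called 6024 genes, and 2 of the 100 splits called as many, the highest 6585. A chance sorting of single libraries was argued against in 7 comparisons and is not excluded for sex. Chance differences between cell pools that 3 libraries share cannot be excluded, as the other splits mix such pools. With a simulated shared spread, sized from the fit on 1 profile per group, the fit on 24 libraries called between 7556 and 7837 unchanged genes. Fits on 1 profile per group, which take that spread into account, called 1618 and 331 genes for aGC in WT FT and KO FT mice, 5 for sex and 94 for the aGC response by sex.

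The first pattern was that calls depended on which of the 8 groups a library belonged to. The term for FT by treatment by sex, which no question of the design names, called 6384 genes, against 7474 for FT averaged over treatment and sex. This is what variation between cell pools that the 3 libraries of a group share would give. With 1 profile per group edgeR called 0 genes for the response difference and for FT after PBS and aGC, with 628, 255 and 1306 at an unadjusted p under 0.05. That fit recovered 12, 32 and 29 of 200 changed genes in simulated data. It counts the terms of sex by treatment, sex by FT and all 3 factors as spread. Sex by treatment alone held 13.3% of the sum of squares between groups. The 0 calls thus cannot tell variation between pools from effects that depend on sex. Such pools could be the animals, the sort or the day of preparation, which the labels do not separate. A response to the microbiota that itself depends on sex and treatment stays open and was not tested, since each group stands alone.

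The second pattern was the high level of Cd8a and naive T cell genes in PBS males and aGC females. Conventional T cells among the sorted cells are a candidate source: in 4 of 4 FT and treatment pairs every library of the Cd8a-high group exceeded every library of the other sex in other Trav segments, 2.85 and 1.56 times after PBS and 2.82 and 2.01 times after aGC (WT FT and KO FT), while Trav11 was 0.611 to 0.804 times as high. Cd8b1 reached 573 and Cd8a 287 CPM in WT FT PBS males, 4 of the 9 CD8 markers (Ccr9, Dapl1, Itgae and Gzmm) stand in other lists too, and a gate on the invariant receptor, not described in the labels, would remove such cells. Mislabelled groups were argued against, with 0 of 8 groups on the side of the other label in Xist, Ddx3y, Irf4, Nr4a1 or Cd83. A sex difference in the aGC response cannot be told apart from a difference between pools, since the sign turned in 2 of 2 FTs and each group is a single set of 3 libraries.

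The third pattern was the lower level of proliferation, ribosomal and oxidative phosphorylation genes in KO FT mice after aGC. A length trend of the libraries was argued against for the proliferation genes, which kept 98.8% of their median log2 difference with an offset for exon length, and cannot be told apart for the 3 lists together, which kept 64.5%, with ribosomal genes at 58.3% and oxidative phosphorylation genes at 53.0%, between the bounds set beforehand. A different share of CD8 T cells was argued against, since the median in males, whose Cd8a level was low in both FTs, was -0.463. An FT effect cannot be told apart from a difference between single cell pools: both sexes had medians below 0, but 0 of the 132 members passed with 1 profile per group in edgeR, with 43 at an unadjusted p under 0.05. A lower response of iNKT cells that grew up with the KO microbiota may be the cause, and animals identified by litter would be needed to test it.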

How the results depend on the processing

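The tests with 1 profile per group, with the exon length offset and without PBS males and aGC females were chosen after seeing the data. With DESeq2, RLE normalization or limma-voom with quality weights all 235 named gene values kept their direction and side of the threshold, with upper-quartile normalization 233, and without a filter 231. Counts stayed within 1.5 times for normalization, tool and filter, and with 1 library left out they ran from 10709 to 11157 and 8930 to 9412 for aGC in WT FT and KO FT mice, 6809 to 7222 for their difference, 4151 to 4937 and 7954 to 8407 for FT after PBS and aGC, 5714 to 6075 for sex, 7969 to 8224 for the aGC response by sex, 6268 to 7062 for the FT effect by sex and 95 to 102 for the gene lists. A lone group of 2 libraries was assumed to vary like the others.

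On 1 profile per group with sex as a term the counts were 1618 and 331 for aGC in WT FT and KO FT mice, 0 for their difference, 0 and 0 for FT after PBS and aGC (edgeR, with 628, 255 and 1306 at an unadjusted p under 0.05 in these 3), and 5 for sex, and with a sex by treatment term 94 genes passed. For the FT effect by sex, a sex by FT term over both treatments called 0 (edgeR, 202 at an unadjusted p under 0.05). With the CD8 marker level in place of sex they were 2555, 847, 0, 0 and 0, with 966, 383 and 2041 at an unadjusted p under 0.05 in the last 3. These fits have 3 residual degrees of freedom. The B cell marker level as a covariate gave 3238, 5393, 3328, 3 and 4175 for the same 5 comparisons, 3765 for the aGC response by sex and 167 for the FT effect by sex. Of the sum of squares of this covariate 97.7% lay between the groups, and why it lowered the counts was not tested. A test against a 1.2-fold change gave 4249, 1514 and 4430 for the response difference and FT after PBS and aGC, and 1496 for sex. An adjusted p under 0.01 gave 2807 for FT after PBS. Replicate number within sex as a block gave 1905 for sex, a block nested in sex, while replicate number as a block gave 10804, 9161 and 4495 for aGC in WT FT and KO FT mice and for FT after PBS, and the numbers showed no pairing (mean r = -0.012 for the same number and 0.006 for different ones). With an estimated correlation 56 list tests passed.

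Without PBS males and aGC females, which sets sex against treatment for aGC, the counts were 9094, 7473, 6427, 4170 and 6861, and 1580 of the 4690 and 5461 of the 8278 FT genes passed in the same direction. These reversed: Tbx21 (-0.26) for aGC in WT FT mice, Zbtb16 (0.26) in KO FT mice, Zbtb16 (-0.052) for FT after PBS, and Ifit3 (1.36) for FT after aGC. Among lists, Y-linked genes for aGC in WT FT mice (adjusted p = 4.39e-13), by construction, interferon-stimulated genes in the response difference (0.455) and for FT after aGC (1.66e-12), and CD8 markers (0.72), macrophage markers (0.72) and proliferation genes (0.00279) for FT after PBS reversed in camera. The offset for exon length reversed Tbx21 in the response difference (0.0079), the B cell covariate Gata3 for FT after aGC (-0.0024) and 1 profile per group Ifit3 for FT after aGC (0.12). The sex by FT term reversed Usp18 (-0.74), Ifit3 (-1.20) and the interferon-stimulated list (camera, adjusted p = 7.07e-05) for the FT effect by sex. In the fit of summed profiles with the CD8 level, CD8 markers for aGC in WT FT mice (0.808) and naive genes (0.572) and CD8 markers (0.633) for FT after PBS reversed in camera. Beyond the construction named, the cause was not tested.

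Sex comparisons could not be run without PBS males and aGC females. Depth limits genes under 0.302 CPM, the highest limit of 3 counts in a library.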

Other observations

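The tests with 1 profile per group were chosen after seeing the data. With aGC in WT FT mice, genes encoded in the mitochondrial genome moved against the nuclear genes of oxidative phosphorylation in females and with them in males. The mean log2 CPM of the 13 mitochondrially encoded genes went from 6.80 to 5.72 in females and from 6.12 to 6.45 in males, and that of the 44 nuclear genes from 7.32 to 7.85 and from 7.29 to 7.99. Averaged over the sexes, of 13 mitochondrially encoded genes 0 rose, 10 fell and 3 did not pass (0 and 10 adjusted over the list alone, camera, adjusted p = 0.101), and 3 were lower in both sexes. In the difference between the KO FT and the WT FT response 9 were higher, 0 were lower and 4 did not pass (9 and 0 adjusted over the list alone, camera, adjusted p = 0.0197, adjusted p = 0.406 with an estimated correlation). This average came from females, since in KO FT mice the mean went from 6.17 to 6.29 in females and from 6.46 to 6.13 in males, a lower response than in WT FT males. For the FT effect by sex after PBS 0 were higher, 9 were lower and 4 did not pass (0 and 11 adjusted over the list alone, camera, adjusted p = 0.00197, adjusted p = 0.383 with an estimated correlation). Their share of all counts stayed between 0.148 and 0.373% in the 24 libraries.

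Genes of protein folding in the endoplasmic reticulum rose with aGC and were lower in KO FT than in WT FT mice after it. Of 22 genes of the unfolded protein response 13 rose, 4 fell and 5 did not pass (13 and 4 adjusted over the list alone, camera, adjusted p = 0.00909, adjusted p = 0.0943 with an estimated correlation) with aGC in KO FT mice, and in the comparison of KO FT with WT FT mice after aGC 3 were higher, 12 were lower and 7 did not pass (3 and 12 adjusted over the list alone, camera, adjusted p = 0.0346, adjusted p = 0.253 with an estimated correlation). Of 22 tissue residency and gut homing genes 13 were higher, 4 were lower and 5 did not pass (13 and 4 adjusted over the list alone, camera, adjusted p = 0.0308, adjusted p = 0.239 with an estimated correlation) in the difference between the KO FT and the WT FT response. With 1 profile per group these 3 tests did not pass (camera, adjusted p = 0.167, 0.254 and 0.251). The 16 markers of IL-10-producing and regulatory T cells rose on balance in KO FT mice as in WT FT mice, since 11 rose, 3 fell and 2 did not pass (11 and 3 adjusted over the list alone, camera, adjusted p = 0.00661). Genes of the TCR complex and its signals fell in KO FT mice too, where of 28 members 3 rose, 20 fell and 5 did not pass (3 and 21 adjusted over the list alone, camera, adjusted p = 1.95e-07, adjusted p = 0.113 with an estimated correlation).

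Markers of other cell types were tested for aGC in WT FT mice. Of 15 NK cell markers 4 rose, 3 fell and 8 did not pass (4 and 3 adjusted over the list alone, camera, adjusted p = 0.205), of 12 plasma cell markers 4 rose, 6 fell and 2 did not pass (4 and 6 adjusted over the list alone, camera, adjusted p = 0.656), and of 3 granulocyte and mast cell markers 0 rose, 0 fell and 3 did not pass (0 and 0 adjusted over the list alone, camera, adjusted p = 0.855). Of 4 erythroid and platelet markers 0 rose, 2 fell and 2 did not pass (0 and 2 adjusted over the list alone, camera, adjusted p = 0.68), and of 7 stromal, endothelial and epithelial markers 2 rose, 2 fell and 3 did not pass (2 and 2 adjusted over the list alone, camera, adjusted p = 0.767).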
